A study of Mus musculus with 104 samples.

How the data were processed

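The deposited value for each probe set and chip is a linear signal intensity, so its unit is intensity, and it was scaled per chip by the authors so that the trimmed mean, with 2% of values removed at each end, was the same on every chip. The trimmed mean recomputed here lay between 150.03 and 150.04 on the 104 chips. The software and the exact algorithm that made the intensities are not given in the sources used here. The deposited chip settings have the unit other, being settings and text, and served only to assign 11 hybridization days and 3 chip lots. Scans of the same chips made again were not used here.

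To each intensity 16 was added before the log2 was taken, which damps the spread of dim probe sets. The 2 chips of a lung were averaged on the log2 scale, because they are repeat measurements of 1 RNA source, which left 52 lungs. Of 22690 probe sets, 64 are array controls and were left out, 691 carry several gene symbols and 1555 carry none. The 20380 with 1 symbol were reduced to the probe set of highest mean for each gene, which gave 12393 genes, of which 4956 had more than 1 probe set. No filter on dim genes and no further normalization was applied.

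All 17 groups were fitted together with limma, with 1 mean per group and no other term, and variances were moderated with a trend on mean intensity (40.4 residual and prior degrees of freedom). Each comparison was a contrast of group means, 2-sided, and p values were adjusted by the method of Benjamini and Hochberg over the 12393 genes of that comparison. A gene was called at an adjusted p under 0.05, and no fold change was required. The averaged phosgene effect weighted the 8 times equally, the change of the phosgene effect with time was an F test over the 8 contrasts, and the change with time in air was an F test over the air groups. Log2 changes are phosgene minus air, or air minus untreated, with the moderated standard error (SE), while intensities are means over lungs with the standard deviation (SD).

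The 32 gene lists (18 of pathways and 14 of cell markers) were written from general knowledge of lung biology before the values were seen. Each list was tested at each time with camera, which compares its members with all other genes and here estimates the correlation between members from the data, and p values were adjusted over the 256 tests. Counts of called members are given over all genes tested and adjusted over the list alone. Fry, which asks whether the members of a list move 1 way on balance, served as another test.

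The lung as a random block was fitted on single chips with the chip letter as a term. All genes shared 1 estimated correlation, 0.283, between the 2 chips of a lung. Genes whose chips correlate more pass too easily, so extra calls of this fit are not added support. The letter is that of the sample description, and for 56 of the 104 chips the title gives the other, so which chip is A or B is uncertain. With the letters of the titles, the block called 1124 genes at 4 h and 902 at 72 h, against 1102 and 904, and 74 list tests against 75, and chip A and chip B alone kept 55 and 53 of the 56 list calls, that of neutrophils at 8 h on both. These title fits were chosen after the values were seen. Hybridization day as a term used the 97 chips with a known day (correlation 0.301), in which 1 of the 3 air lungs of 72 h shares its days with other lungs. The other settings changed the offset, the normalization, the filter, the probe set, the chip, the weights, the control group or the lungs included, 1 at a time.

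The same code was run on simulated values with known changes, which tests the code, not error rates in real lungs. Of 100 genes given a log2 change of 1 at 4 h, 90 were called (mean estimate 1.03). Of 100 given one of 2, 100 were called (1.98). At 4 h 11 of 12393 genes were false calls, and 0 were called at other times. The shifted list had an adjusted p of 1.85e-09, and 0 other tests of 256 passed. Versions were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.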

Results

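The series measured messenger RNA in whole mouse lung on expression microarrays (oligonucleotide chips, the first array of a 2-array mouse set) after exposure to phosgene, a reactive gas that injures the lung. 104 chips covered 52 numbered lungs, with 2 chips per lung. The lungs formed 17 groups: 3 untreated lungs, 3 air lungs at each of 8 times except 4 at 48 h, and 3 phosgene lungs at each of the 8 times. Of the air lungs 5, 1 of 8 h and 2 each of 48 h and 72 h, carry lung numbers apart from the rest. The times are labelled 0.5, 1, 4, 8, 12, 24, 48 and 72 without a unit, and the phosgene amount is labelled 32 mg, so hours, and a concentration per volume of air, rest on knowledge of the study. The authors scaled each chip to a common trimmed mean, and chip medians ran from 68.2 to 90.1 intensity units. The labels do not state that a numbered lung is 1 animal, so every p describes the spread between numbered lungs alone, and the number of arrays limits the precision. For each of 12393 genes, the phosgene lungs of a time were compared with the air lungs of that time, which asks which lung genes respond to phosgene at that time.

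In all, 2164 genes passed an adjusted p under 0.05 at 1 or more times, 1020 of them higher and 1159 lower in phosgene lungs with 15 counted in both, and 140 passed at 4 or more times. Atf3, a stress-induced transcription factor, Gclc, the catalytic subunit of the rate-limiting enzyme of glutathione synthesis, and Mt2, a metal-binding metallothionein, rose at all 8 times, with log2 changes of 1.23 to 4.46, 0.91 to 3.69 and 1.41 to 3.35. Their calls held whichever lung was left out at 5, 7 and 7 of the 8 times, all but 24, 48 and 72 h for Atf3, 72 h for Gclc and 0.5 h for Mt2. The genes named at single times are those of largest change whose 3 phosgene lungs all lay beyond all air lungs, an arrangement that chance gives in 10% of genes for 3 against 3 lungs and 5.71% for 3 against 4. Among these, genes whose call held whichever lung was left out were preferred, a choice made after the values were seen. Folds are ratios of the intensity plus 16, the offset, and so differ from ratios of the plain intensities, most for dim genes. Of 149 named genes at single times, 21 did not pass against untreated lungs in place of the air lungs of the time, and the change was smaller by 1 log2 or more for 3 and larger for 6. Hspa1a and Hspa1b are near-identical in sequence, so their separate values are uncertain. The 32 gene lists were fixed before the values were seen, and 56 of the 256 tests of a list at a time passed with a correlation estimated from the data. A preset correlation of 0.01 gave 123 calls, and 56 of these held with the estimated correlation. Of the 56 list calls, 41 held whichever lung was left out, and 34 of those also held in every other setting tried. The median, the mean and the test of a list differed in sign in 28 of the 256 tests and in 0 of the 56 calls. A member of a list is counted as stable if its call held whichever lung of the 2 groups was left out, which was so for 385 of 664 member calls over all lists and times. For the fits of single chips (with the lung as a random block, and with hybridization day or chip lot as a further term) lists were tested from the moderated t of each gene. On averaged chips that form called 61 tests, the 56 among them. The stable counts, this form on averaged chips and the test within hybridization days were chosen after the values were seen.

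**Figure D1:**
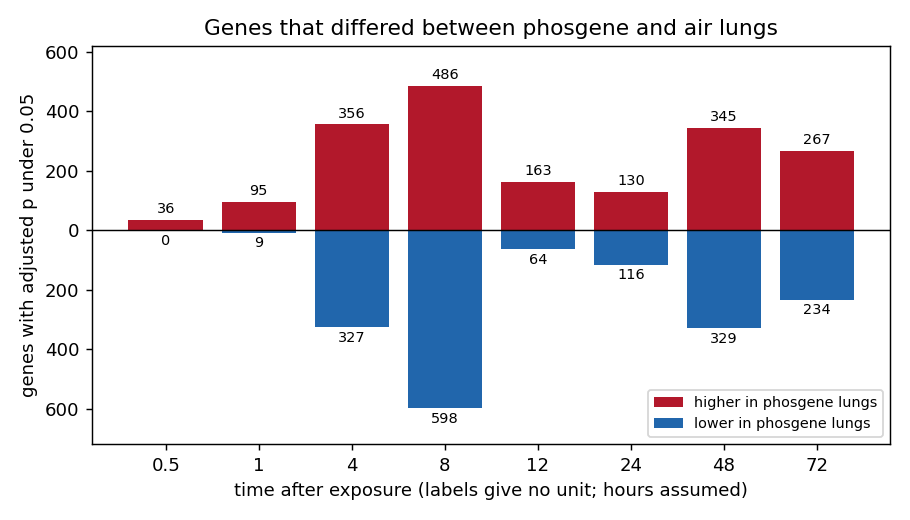
Genes with an adjusted p under 0.05 (vertical axis, number of genes) at each time after exposure (horizontal axis, h), with bars for genes higher and genes lower in phosgene lungs than in air lungs. The largest numbers, 486 higher and 598 lower, stand at 8 h, and 0 genes were lower at 0.5 h.

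At 0.5 h, the genes of largest rise included transcription factors and chaperones. Atf3 was 14.3-fold higher (log2 change 3.84 ± 0.33 SE, adjusted p = 7.63e-11). Its intensity was 508 ± 108 (SD, n = 3) against 23.2 ± 10.7 (SD, n = 3) in air lungs without the offset. Egr1 was 12.2-fold and Fos 8.91-fold higher, both immediate early transcription factors, and Arc, an activity-induced immediate early gene, was 6.60-fold higher (log2 change 2.72 ± 0.13 SE, adjusted p = 1.19e-18). The inducible heat shock protein Hspa1a was 8.13-fold higher and Hmox1, heme oxygenase, 7.27-fold. Of 22 immediate early genes, 13 rose, 0 fell and 9 were not called (13 stable, 17 higher and 0 lower adjusted over the list alone, median log2 change 1.19, camera adjusted p = 7.4e-08). Of 18 glucocorticoid-induced genes, 4 rose, 0 fell and 14 were not called (2 stable, 6 higher and 0 lower adjusted over the list alone, median log2 change 0.33, camera adjusted p = 0.0078). Of 15 heat shock and folding genes, 3 rose, 0 fell and 12 were not called (3 stable, 5 higher and 0 lower adjusted over the list alone, median log2 change 0.48, camera adjusted p = 0.0039). By limma, 36 genes rose and 0 fell, with 442 genes at an unadjusted p under 0.05. All 10 genes of largest rise kept their call whichever lung was left out. The glucocorticoid and heat shock list calls were lost without phosgene replicate 3 (adjusted p = 0.108 and 0.0981), while without phosgene replicate 1 the glutathione, endoplasmic reticulum stress and ciliated cell lists were called (adjusted p = 0.0216, 0.0059 and 0.0167). 56 genes passed with the lung as a random block, including all 36. 61 passed with hybridization day as a term, including 35 of the 36. Fitting the 6 lungs of 0.5 h alone gave 32. With the block, the day and the lot, the glutathione list was called (0.0282, 0.026 and 0.0302) and so was the NRF2 list (0.0222, 0.0476 and 0.0397), and the endoplasmic reticulum list with the block and the day (0.0376 and 0.0436), with medians of only 0.03 and 0.01. On chip A alone the glutathione list was called as well (0.0222).

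At 1 h, the genes of largest rise included transcription factors, chaperones and oxidant defence genes. Atf3 was 22.0-fold higher (log2 change 4.46 ± 0.33 SE, adjusted p = 6.01e-13), Hspa1a 17.1-fold and Hmox1 15.5-fold (log2 change 3.95 ± 0.30 SE, adjusted p = 1.73e-12). Dnajb1, a partner chaperone of the inducible heat shock proteins, was 10.2-fold higher, and Osgin1, a growth inhibitor induced by oxidative stress, 9.05-fold. Of 22 immediate early genes, 16 rose, 0 fell and 6 were not called (15 stable, 18 higher and 0 lower adjusted over the list alone, median log2 change 1.24, camera adjusted p = 1.76e-07). Jun had a log2 change of 1.64. Of 15 heat shock and folding genes, 10 rose, 0 fell and 5 were not called (9 stable, 13 higher and 0 lower adjusted over the list alone, median log2 change 0.98, camera adjusted p = 6.48e-05). Of 21 endoplasmic reticulum stress and ATF4 target genes, 6 rose, 0 fell and 15 were not called (4 stable, 8 higher and 0 lower adjusted over the list alone, median log2 change 0.32, camera adjusted p = 7.7e-05). Of 18 NRF2 target enzymes, the antioxidant enzymes under the transcription factor NRF2, 3 rose, 0 fell and 15 were not called (3 stable, 6 higher and 0 lower adjusted over the list alone, median log2 change 0.25, camera adjusted p = 0.004). Of 18 glucocorticoid-induced genes, 5 rose, 0 fell and 13 were not called (4 stable, 10 higher and 0 lower adjusted over the list alone, median log2 change 0.39, camera adjusted p = 0.0039). Of 16 p53 target genes, 2 rose, 0 fell and 14 were not called (1 stable, 5 higher and 0 lower adjusted over the list alone, median log2 change 0.02, camera adjusted p = 0.0393). Of 7 red cell genes, 0 rose, 1 fell and 6 were not called (0 stable, 0 higher and 2 lower adjusted over the list alone, median log2 change -0.44, camera adjusted p = 0.014). In all, 95 genes rose and 9 fell. The 9 that fell had log2 changes between -0.81 (Bpgm) and -0.41 (Smarca2), and each lost its call without at least 1 lung. The number of lower genes was 2, 5 and 29 without phosgene replicates 1, 2 and 3 and 3, 26 and 9 without air replicates 1, 2 and 3. Of the 9, 8, 8 and 2 lost their call without those phosgene lungs and 6, 7 and 8 without those air lungs, of which replicate 1 stood apart in Rag1 and Adipoq (log2 8.31 and 9.50), genes of developing lymphocytes and of fat. The p53 list call was lost without air replicate 1 or 3 (adjusted p = 0.0956 and 0.0904) and without phosgene replicate 2 or 3 (0.0869 and 0.104), and the red cell call without air replicate 2 (0.122). The p53 call was also lost with median centring (0.107) and on chip B alone (0.142), and the red cell call on chip A alone (0.0603). Without air replicate 2 the cell division and DNA replication lists were called (adjusted p = 0.013 and 0.0314), without air replicate 1 the endothelial list (0.0417) and without air replicate 3 the T and NK cell list (0.0373). 198 genes passed with the lung as a random block, including 100 of the 104. 239 passed with hybridization day as a term, including 102. Fitting the 6 lungs of this time alone gave 56. The glutathione list was called with the block, the day and the lot (0.0302, 0.0194 and 0.0148) and with array weights (0.0393).

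At 4 h, the largest rises included those of chaperones and antioxidant enzymes. Hspa1b was 41.9-fold higher (log2 change 5.39 ± 0.38 SE, adjusted p = 1.77e-13) and Hmox1 22.1-fold (log2 change 4.46 ± 0.30 SE, adjusted p = 8.47e-14). The Hmox1 intensity was 1568 ± 174 (SD, n = 3) against 56.1 ± 3.64 (SD, n = 3) in air lungs without the offset. Srxn1, the sulfiredoxin that restores oxidised peroxiredoxins, was 8.38-fold higher, Gclc 7.57-fold and Sfn, an epithelial adaptor protein, 6.55-fold. Cckar, a cholecystokinin receptor, was 2.58-fold lower (log2 change -1.36 ± 0.21 SE, adjusted p = 2.6e-05) and Derl3, a protein of endoplasmic reticulum degradation, was also lower (adjusted p = 0.000543). Of 18 NRF2 target enzymes, 14 rose, 0 fell and 4 were not called (12 stable, 15 higher and 0 lower adjusted over the list alone, median log2 change 0.96, camera adjusted p = 7.58e-05). Txnrd1, a thioredoxin reductase, had a log2 change of 2.17 ± 0.19 SE that did not pass with its next brightest probe set. Of 18 glucocorticoid-induced genes, 14 rose, 0 fell and 4 were not called (13 stable, 16 higher and 0 lower adjusted over the list alone, median log2 change 1.16, camera adjusted p = 0.000153). These included Errfi1 (1.87), Ddit4 (1.39) and Tsc22d3 (1.28). Of 15 heat shock and folding genes, 13 rose, 0 fell and 2 were not called (12 stable, 13 higher and 0 lower adjusted over the list alone, median log2 change 1.37, camera adjusted p = 0.000137). The mitochondrial chaperone Hspd1 had a log2 change of 1.48. Of 21 endoplasmic reticulum stress and ATF4 target genes, 9 rose, 0 fell and 12 were not called (7 stable, 11 higher and 0 lower adjusted over the list alone, median log2 change 0.48, camera adjusted p = 6.48e-05). Of 22 immediate early genes, 11 rose, 0 fell and 11 were not called (9 stable, 14 higher and 1 lower adjusted over the list alone, median log2 change 0.72, camera adjusted p = 0.0039). Of 25 genes of glutathione synthesis and use, 6 rose, 0 fell and 19 were not called (6 stable, 8 higher and 1 lower adjusted over the list alone, median log2 change 0.22, camera adjusted p = 0.0039). Of 16 p53 target genes, 3 rose, 0 fell and 13 were not called (2 stable, 3 higher and 0 lower adjusted over the list alone, median log2 change 0.18, camera adjusted p = 0.0124). Of 25 matrix, wound repair and fibrinolysis genes, 6 rose, 1 fell and 18 were not called (5 stable, 8 higher and 1 lower adjusted over the list alone, median log2 change 0.16, camera adjusted p = 0.0328). In all, 356 genes rose and 327 fell, so 52.1% of called genes were higher, a share that was 80.3% with each chip centred on its median. All 10 of the largest rises and 2 of the 10 largest falls, those of Cckar and Derl3, kept their call whichever lung was left out. Leaving out air replicate 2 gave 330 genes and phosgene replicate 2 gave 335. Without phosgene replicate 3 the p53 and matrix calls were lost (adjusted p = 0.0815 and 0.0688), as was the matrix call without air replicate 3 (0.0546), with chips centred on their medians (0.164) with quantile normalization (0.141), with the Gapdh ratio as a covariate (0.0586) and on chip lot 1 alone (0.0547). The endothelial list, with 7 of 22 members lower, was called without air replicate 2 or 3 or phosgene replicate 2 (0.0496, 0.0414 and 0.0433), and the list of other antioxidant enzymes without air replicate 1 (0.0251). 1102 genes passed with the lung as a random block, including 639 of the 683. The fit with hybridization day as a term kept 541. The 6 lungs of 4 h fitted alone gave 361. With the block, the day and the lot, the endothelial list was called lower (0.009, 0.0016 and 0.0018) and the other antioxidant list higher (0.0028, 0.0046 and 0.004, medians of 0.06, 0.05 and 0.01), which the moderated t of averaged chips also gave (0.044 and 0.0191). The endothelial list was also called with quantile normalization (0.0127), on chip B alone (0.022) and on lot 1 alone (0.0124).

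At 8 h, the largest rises included those of a glutathione gene, a chaperone and a metallothionein. Gclc was 12.9-fold higher (log2 change 3.69 ± 0.22 SE, adjusted p = 1.31e-15), with an intensity of 2589 ± 369 (SD, n = 3) against 185 ± 29.4 (SD, n = 3) in air lungs without the offset, and its partner subunit Gclm had a log2 change of 2.37 ± 0.24 SE. The air level of Gclc was lowest at 8 h (log2 7.64 against 8.29 to 8.78 at the other times), and against untreated lungs the log2 change of Gclc was 2.90 at 8 h and 3.03 at 4 h. Hspa1a was 29.0-fold higher, Mt2 10.2-fold and Sfn 9.83-fold. Tcf21, a transcription factor of lung mesenchyme, was 2.44-fold lower (log2 change -1.29 ± 0.19 SE, adjusted p = 7.42e-06), Cckar 2.67-fold lower and Tppp3, a tubulin-binding protein on the ciliated cell list, 2.39-fold lower. Of 18 NRF2 target enzymes, 14 rose, 0 fell and 4 were not called (12 stable, 15 higher and 0 lower adjusted over the list alone, median log2 change 1.03, camera adjusted p = 7.7e-05). Of 25 genes of glutathione synthesis and use, 8 rose, 0 fell and 17 were not called (7 stable, 8 higher and 0 lower adjusted over the list alone, median log2 change 0.28, camera adjusted p = 0.0111). Gsta2 and Gpx2 had log2 changes of 2.09 and 1.80. Of 22 immediate early genes, 16 rose, 0 fell and 6 were not called (12 stable, 19 higher and 0 lower adjusted over the list alone, median log2 change 0.93, camera adjusted p = 0.000309). Of 15 heat shock and folding genes, 13 rose, 0 fell and 2 were not called (10 stable, 13 higher and 0 lower adjusted over the list alone, median log2 change 1.21, camera adjusted p = 0.000739). Of 21 endoplasmic reticulum stress and ATF4 target genes, 11 rose, 0 fell and 10 were not called (7 stable, 12 higher and 0 lower adjusted over the list alone, median log2 change 0.49, camera adjusted p = 7.7e-05). They included Asns (1.18), Slc3a2 (1.24) and Atf4 (1.09). Of 18 glucocorticoid-induced genes, 9 rose, 0 fell and 9 were not called (7 stable, 14 higher and 0 lower adjusted over the list alone, median log2 change 0.76, camera adjusted p = 0.0039). Of 16 p53 target genes, 6 rose, 0 fell and 10 were not called (3 stable, 6 higher and 0 lower adjusted over the list alone, median log2 change 0.36, camera adjusted p = 0.0039). The cell cycle inhibitor Cdkn1a had a log2 change of 1.81 ± 0.27 SE. Of 25 matrix, wound repair and fibrinolysis genes, 9 rose, 0 fell and 16 were not called (9 stable, 10 higher and 4 lower adjusted over the list alone, median log2 change 0.47, camera adjusted p = 0.0104). Of 16 neutrophil genes, 5 rose, 0 fell and 11 were not called (4 stable, 5 higher and 0 lower adjusted over the list alone, median log2 change 0.42, camera adjusted p = 0.0148). Il1r2 had a log2 change of 1.94, and the neutrophil protein genes S100a8 and S100a9 had changes of 2.40 and 2.43.

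In all, 486 genes rose and 598 fell at 8 h, so 44.8% of called genes were higher, a share that was 60.6% with each chip centred on its median. All 10 of the largest rises and 7 of the 10 largest falls kept their call whichever lung was left out. Of those 7, Tnfrsf19 lost its call with its next brightest probe set, and Cckar, Lrat, Cyp4f15, Tcf21, Tppp3 and Nrep held in every setting. Leaving out air replicate 2 gave 711 genes. The neutrophil call was lost without phosgene replicate 2 (adjusted p = 0.0532) and on chip A alone (0.0538), while the endothelial list, not called with all lungs (0.0978), was called without air replicate 1 (0.0469) or phosgene replicate 3 (0.0232). Centring chips on their medians ended the glutathione and matrix calls of 8 h (adjusted p = 0.0553 and 0.062). Of the 1084 genes, 1025 passed again with the lung as a random block and 786 with hybridization day as a term. Fitting the 6 lungs of 8 h alone gave 218 genes. With the block, the day and the lot, the endothelial list was called lower at 8 h (0.0222, 0.0298 and 0.0163), and so was the club cell list (0.0224, 0.006 and 0.0078, with 0.0196 on lot 1 alone).

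At 12 h, the largest rises included those of acute phase genes. Serpina3n, a serine protease inhibitor of the acute phase, was 6.63-fold higher (log2 change 2.73 ± 0.33 SE, adjusted p = 7.39e-07). Its intensity was 566 ± 152 (SD, n = 3) against 79.2 ± 49.8 (SD, n = 3) in air lungs without the offset. Hspa1a was 8.03-fold higher, Mt2 5.58-fold, Blvrb, a biliverdin reductase, 5.32-fold, Lrg1, a glycoprotein of the acute phase, 4.91-fold and Socs3, an inhibitor of cytokine signalling, 4.04-fold. Abcg1, a cholesterol exporter, was 1.66-fold lower (log2 change -0.73 ± 0.15 SE, adjusted p = 0.0021). Of 18 NRF2 target enzymes, 9 rose, 0 fell and 9 were not called (8 stable, 13 higher and 0 lower adjusted over the list alone, median log2 change 0.64, camera adjusted p = 0.000538). Of 19 acute phase proteins, 4 rose, 0 fell and 15 were not called (3 stable, 7 higher and 0 lower adjusted over the list alone, median log2 change 0.43, camera adjusted p = 0.0021). Of 21 endoplasmic reticulum stress and ATF4 target genes, 4 rose, 0 fell and 17 were not called (0 stable, 7 higher and 0 lower adjusted over the list alone, median log2 change 0.15, camera adjusted p = 0.0039). Of 25 glutathione genes, 4 rose, 0 fell and 21 were not called (2 stable, 7 higher and 0 lower adjusted over the list alone, median log2 change 0.18, camera adjusted p = 0.007). Of 25 matrix, wound repair and fibrinolysis genes, 8 rose, 0 fell and 17 were not called (6 stable, 11 higher and 3 lower adjusted over the list alone, median log2 change 0.35, camera adjusted p = 0.0092). Of 18 glucocorticoid-induced genes, 7 rose, 0 fell and 11 were not called (5 stable, 7 higher and 0 lower adjusted over the list alone, median log2 change 0.24, camera adjusted p = 0.0122). Of 22 immediate early genes, 5 rose, 0 fell and 17 were not called (4 stable, 8 higher and 0 lower adjusted over the list alone, median log2 change 0.37, camera adjusted p = 0.0328). Of 22 endothelial cell markers, 0 rose, 3 fell and 19 were not called (1 stable, 0 higher and 11 lower adjusted over the list alone, median log2 change -0.41, camera adjusted p = 0.0227). In all, 163 genes rose and 64 fell, so 71.8% of called genes were higher, a share that was 86.8% with each chip centred on its median. Of the 10 largest rises 9 kept their call whichever lung was left out, and of the 10 largest falls 3 did, of which only that of Abcg1 held in every setting. Leaving out air replicates 1, 2 and 3 gave 133, 139 and 125 genes, and leaving out phosgene replicate 1 gave 89. The immediate early call was lost without air replicate 1 or phosgene replicate 2 or 3 (adjusted p = 0.0673, 0.0545 and 0.0558), the glucocorticoid call without phosgene replicate 1 (0.0576) and the endothelial call without phosgene replicate 3 (0.0704). Centring chips on their medians ended the matrix, glutathione, immediate early and endoplasmic reticulum calls (0.062, 0.052, 0.0662 and 0.0784), and quantile normalization the immediate early call (0.0587). The other antioxidant list was called without air replicate 1 or 2 or phosgene replicate 2 (0.0367, 0.0438 and 0.0495), and the heat shock list without phosgene replicate 2 (0.0463). 555 genes passed with the lung as a random block, including 214 of the 227. 529 passed with hybridization day as a term, including 204. The 6 lungs of 12 h fitted alone gave 44. The heat shock list was called with the block, the day and the lot (0.0128, 0.0368 and 0.0108), and so was the other antioxidant list (0.0044, 0.0272 and 0.0118, with 0.0179 from the moderated t of averaged chips and 0.0227 on chip B alone), although its median lay near 0 (0.000378, -0.03 and -0.01). The day also gave alveolar type 1 cells, lower (0.0298), and neutrophils, higher (0.0318).

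At 24 h, Timp1, an inhibitor of matrix-degrading proteases, was 6.39-fold higher (log2 change 2.68 ± 0.27 SE, adjusted p = 2.46e-08). Its intensity was 597 ± 171 (SD, n = 3) against 80.0 ± 16.4 (SD, n = 3) in air lungs without the offset. Hspa1a was 8.56-fold higher, Lrg1 5.21-fold, Serpina3n 4.74-fold and Lcn2, an iron-binding acute phase protein, 4.00-fold. Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, was 3.96-fold lower (log2 change -1.99 ± 0.29 SE, adjusted p = 3.12e-05), Pon1, a paraoxonase, 3.03-fold lower and Slc7a10, an amino acid transporter, 2.23-fold lower. Of 19 acute phase proteins, 4 rose, 0 fell and 15 were not called (4 stable, 7 higher and 0 lower adjusted over the list alone, median log2 change 0.21, camera adjusted p = 0.000474). Of 25 matrix, wound repair and fibrinolysis genes, 9 rose, 1 fell and 15 were not called (6 stable, 12 higher and 4 lower adjusted over the list alone, median log2 change 0.25, camera adjusted p = 0.0092). The epithelial keratins Krt18, Krt8 and Krt19 had log2 changes of 1.15, 1.05 and 0.97. Of 18 glucocorticoid-induced genes, 7 rose, 0 fell and 11 were not called (5 stable, 10 higher and 0 lower adjusted over the list alone, median log2 change 0.67, camera adjusted p = 0.0014). Of 18 NRF2 target enzymes, 5 rose, 0 fell and 13 were not called (2 stable, 11 higher and 0 lower adjusted over the list alone, median log2 change 0.42, camera adjusted p = 0.0076). Of 22 immediate early genes, 4 rose, 0 fell and 18 were not called (0 stable, 7 higher and 0 lower adjusted over the list alone, median log2 change 0.45, camera adjusted p = 0.0296). Of 21 endoplasmic reticulum stress and ATF4 target genes, 3 rose, 0 fell and 18 were not called (2 stable, 5 higher and 0 lower adjusted over the list alone, median log2 change 0.16, camera adjusted p = 0.0414). In all, 130 genes rose and 116 fell. Of the 10 largest rises 9 kept their call whichever lung was left out, and of the 10 largest falls 4 did, those of Cyp1a1, Pon1, Nrep and Slc7a10. Leaving out air replicates 1, 2 and 3 gave 159, 135 and 136 genes, and leaving out phosgene replicates 1 and 3 gave 113 and 94. The immediate early call was lost without air replicate 2 or 3 or phosgene replicate 1 or 3 (adjusted p = 0.0599, 0.0603, 0.0902 and 0.0681) and with median centring (0.0537), which also ended the matrix call (0.0537). The endoplasmic reticulum call was lost without air replicate 1 or 3 or phosgene replicate 1 or 3 (0.0714, 0.0603, 0.0524 and 0.117), with median centring (0.234) or quantile normalization (0.0615), without the air lungs numbered apart (0.0583), with the Gapdh ratio as a covariate (0.0782), on chip A alone (0.107) and on chip lot 1 alone (0.0858). The p53 list was called without air replicate 3 (0.0359) or phosgene replicate 2 (0.0198), and the clock list without phosgene replicate 3 (0.021). 471 genes passed with the lung as a random block, including 233 of the 246. 546 passed with hybridization day as a term, including 234. Fitting the 6 lungs of 24 h alone gave 159. With the block, the day and the lot, the other antioxidant list was called (0.025, 0.0333 and 0.0413), although its median lay near 0 (-0.01, -0.01 and 0.01). With the block and the lot, the p53 list was called (0.0268 and 0.037, with 0.0415 from the moderated t of averaged chips, 0.048 with offset 1, 0.0176 on chip A alone, 0.048 on lot 1 alone and 0.039 with array weights), as were the alveolar type 1 (0.0472 and 0.0322) and club cell lists (0.023 and 0.0154), both lower. T and NK cells were called lower with the day (0.0425). On lot 1 alone the club cell list was called (0.0308), and so was the clock list (0.0435), which chip A alone also gave (0.0281).

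At 48 h, the cell division, DNA replication and acute phase lists were called higher, and the endothelial and red cell lists lower. Lrg1 was 6.55-fold higher (log2 change 2.71 ± 0.27 SE, adjusted p = 7.95e-09). Its intensity was 1778 ± 294 (SD, n = 3) against 264 ± 78.8 (SD, n = 4) in air lungs without the offset. Retnla, a secreted resistin-like protein of macrophages, was 6.05-fold higher, Arg1, arginase, 4.74-fold and Rrm2, a subunit of ribonucleotide reductase, 3.68-fold (log2 change 1.88 ± 0.21 SE, adjusted p = 5.85e-08). Igfbp3, a binding protein of insulin-like growth factors, was 3.21-fold lower (log2 change -1.68 ± 0.33 SE, adjusted p = 0.000766), Cyp1a1 3.03-fold lower and Acaa1b, a peroxisomal thiolase, 2.44-fold lower. Of 24 cell division genes, 21 rose, 0 fell and 3 were not called (17 stable, 22 higher and 0 lower adjusted over the list alone, median log2 change 1.00, camera adjusted p = 0.0031). The mitotic kinase Cdk1 was 3.91-fold higher, a call that ended with untreated lungs as the control, and the mitotic checkpoint kinase Bub1b had a log2 change of 1.57 ± 0.19 SE. Of 21 DNA replication genes, 12 rose, 0 fell and 9 were not called (7 stable, 18 higher and 0 lower adjusted over the list alone, median log2 change 0.64, camera adjusted p = 0.000474). Uhrf1, a chromatin protein of replicating cells, had a log2 change of 1.44. Of 19 acute phase proteins, 7 rose, 0 fell and 12 were not called (4 stable, 8 higher and 0 lower adjusted over the list alone, median log2 change 0.43, camera adjusted p = 0.000856). Orm1 and Itih4 had log2 changes of 1.30 and 1.23. Of 25 matrix, wound repair and fibrinolysis genes, 9 rose, 0 fell and 16 were not called (6 stable, 12 higher and 1 lower adjusted over the list alone, median log2 change 0.38, camera adjusted p = 0.0039). Among 18 glucocorticoid-induced genes, 7 rose, 0 fell and 11 were not called (5 stable, 9 higher and 0 lower adjusted over the list alone, median log2 change 0.48, camera adjusted p = 0.0195). Of 21 macrophage and monocyte markers, 7 rose, 0 fell and 14 were not called (4 stable, 9 higher and 2 lower adjusted over the list alone, median log2 change 0.52, camera adjusted p = 0.0328). Of 22 endothelial cell markers, 0 rose, 8 fell and 14 were not called (4 stable, 0 higher and 10 lower adjusted over the list alone, median log2 change -0.41, camera adjusted p = 0.0039). Of 7 red cell genes, 0 rose, 4 fell and 3 were not called (3 stable, 0 higher and 4 lower adjusted over the list alone, median log2 change -0.64, camera adjusted p = 0.0039), with Alas2, the first enzyme of heme synthesis in red cells, at -0.91.

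In all, 345 genes rose and 329 fell at 48 h. All 10 of the largest rises and 9 of the 10 largest falls kept their call whichever lung was left out, and the falls of Pgam2, Slc4a1 and Prkcq were not called without the air lungs numbered apart. Without those 5 lungs, which leaves 2 of the 4 air lungs of this time, 382 genes passed at 48 h and the glucocorticoid and macrophage calls were lost (adjusted p = 0.0559 and 0.0804). Leaving out phosgene replicate 3 gave 392 genes. The macrophage call was lost without phosgene replicate 2 (0.101), and centring chips on their medians ended the glucocorticoid call (0.053). 1098 genes passed with the lung as a random block, including 656 of the 674. 1023 passed with hybridization day as a term, including 620. Fitting the 7 lungs of 48 h alone gave 446. The cytochrome P450 list was called lower with the block, the day and the lot (0.0224, 0.0298 and 0.0168), the other antioxidant list with the block and the day (0.0432 and 0.0436, medians of 0.01 and 0.04) and the neutrophil list with the block (0.0492).

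At 72 h, the macrophage, acute phase and DNA replication lists were called higher, and the endothelial and red cell lists lower. Clu, clusterin, an extracellular chaperone, was 5.27-fold higher (log2 change 2.40 ± 0.25 SE, adjusted p = 5.91e-08), Retnla 5.62-fold and Gpnmb, a glycoprotein of macrophages, 4.00-fold. The Gpnmb intensity was 269 ± 134 (SD, n = 3) against 50.4 ± 13.5 (SD, n = 3) in air lungs without the offset. Timp1 was 3.44-fold higher and Apoc2, a cofactor of lipoprotein lipase, 3.49-fold. Alas2 was 3.65-fold lower (log2 change -1.87 ± 0.21 SE, adjusted p = 1.97e-07). Of 21 macrophage and monocyte markers, 9 rose, 0 fell and 12 were not called (5 stable, 12 higher and 0 lower adjusted over the list alone, median log2 change 0.61, camera adjusted p = 0.0058). The lysosomal membrane protein gene Cd68 had a log2 change of 1.11 and the protease gene Ctsk one of 2.20. Of 19 acute phase proteins, 4 rose, 0 fell and 15 were not called (2 stable, 7 higher and 0 lower adjusted over the list alone, median log2 change 0.42, camera adjusted p = 0.0039). Of 24 cell division genes, 14 rose, 0 fell and 10 were not called (4 stable, 20 higher and 0 lower adjusted over the list alone, median log2 change 0.74, camera adjusted p = 0.0146). Of 21 DNA replication genes, 8 rose, 0 fell and 13 were not called (3 stable, 18 higher and 0 lower adjusted over the list alone, median log2 change 0.54, camera adjusted p = 0.0024). Of 22 endothelial cell markers, 0 rose, 9 fell and 13 were not called (5 stable, 0 higher and 19 lower adjusted over the list alone, median log2 change -0.53, camera adjusted p = 0.000362). The endothelial receptor kinase gene Tie1 had a log2 change of -1.05, which did not pass without air replicate 3 or phosgene replicate 3 (adjusted p = 0.123 and 0.0776). Of 7 red cell genes, 0 rose, 3 fell and 4 were not called (2 stable, 0 higher and 4 lower adjusted over the list alone, median log2 change -0.72, camera adjusted p = 0.0039). Of 14 cytochrome P450 and aryl hydrocarbon genes, 0 rose, 2 fell and 12 were not called (1 stable, 0 higher and 3 lower adjusted over the list alone, median log2 change -0.24, camera adjusted p = 0.0368). The largest change was that of H2-Ea, a class II histocompatibility gene, at 7.33-fold higher (log2 change 2.87 ± 0.80 SE, adjusted p = 0.0299), which did not pass without any 1 of air replicates 1, 2 and 3 (0.0581, 0.0691 and 0.118) or phosgene replicates 2 and 3 (0.101 and 0.112), or on chip A alone.

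In all, 267 genes rose and 234 fell at 72 h. Of the 10 largest rises 9 kept their call whichever lung was left out, and of the 10 largest falls 5 did. Of the 3 air lungs of this time, 2 are among the 5 numbered apart. Fits without those 5, on lot 1 alone, or with hybridization day or chip lot as a term compare with 1 air lung of 72 h. The other 2 were left out or had no day or lot shared with other lungs, and the spread comes from other groups. Calls lost or gained in these fits at 72 h are not read here, and how far the 72 h results rest on those 2 lungs stays open. Leaving out air replicate 3 gave 227 genes, phosgene replicate 2 gave 233 and phosgene replicate 3 gave 247. The cell division call was lost without air replicate 1 (adjusted p = 0.0606), and the cytochrome P450 call without air replicate 2 or phosgene replicate 2 (0.115 and 0.101), with median centring (0.114), with the Gapdh ratio as a covariate (0.054), on chip B alone (0.0534) and with array weights (0.0655). Without phosgene replicate 3 the cholesterol list was called (0.0254), and without phosgene replicate 1 the smooth muscle and fibroblast list (0.0161). 904 genes passed with the lung as a random block, including 478 of the 501. The 6 lungs of 72 h fitted alone gave 65. With the block, the cardiac and skeletal muscle list was called lower (0.0328), and so was the smooth muscle and fibroblast list (0.0224, with 0.0378 from the moderated t of averaged chips, 0.0218 with quantile normalization and 0.0483 on chip B alone).

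**Figure D2:**
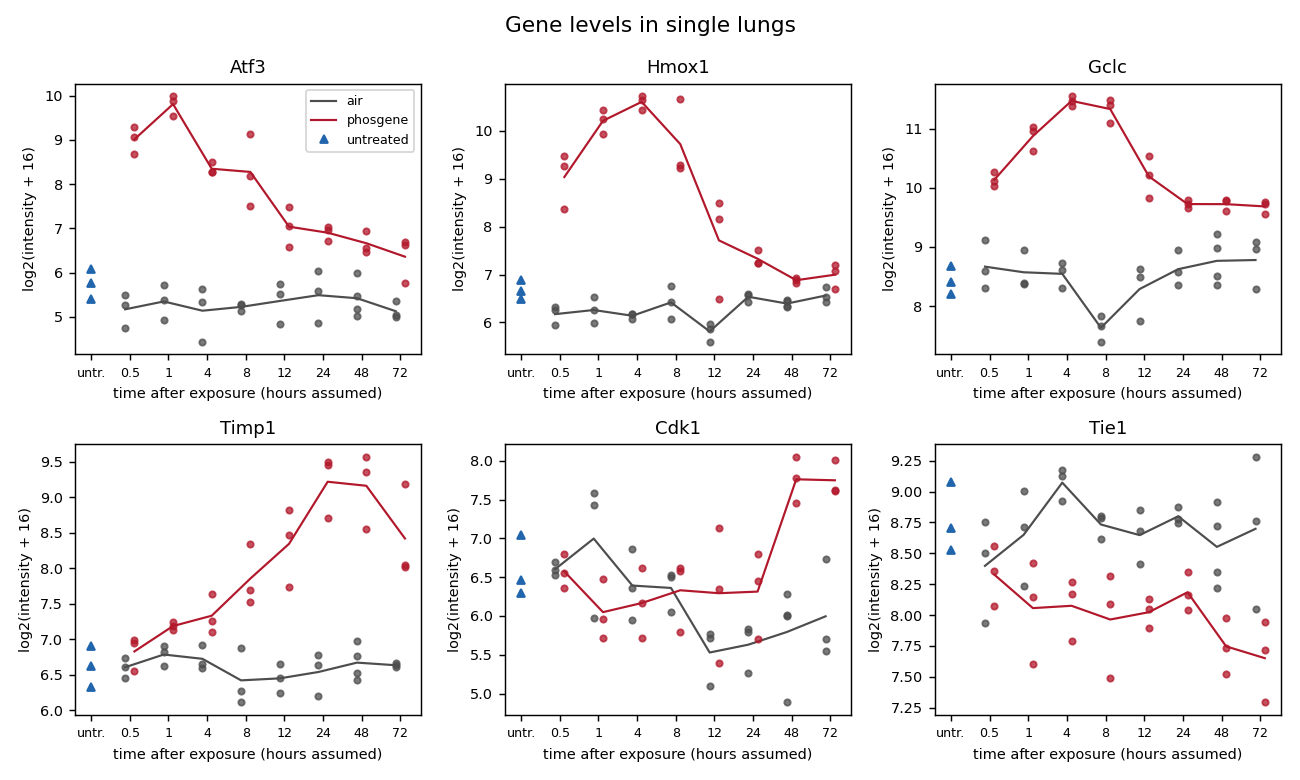
Log2 of the intensity plus 16 (vertical axis) of Atf3, Hmox1, Gclc, Timp1, Cdk1 and Tie1 at each time (horizontal axis, h, times evenly spaced), with points for single lungs and a line through the mean of the phosgene and of the air lungs, and untreated lungs at the left. The log2 change of Atf3 was 3.84 at 0.5 h, that of Gclc 3.69 at 8 h and that of Cdk1 1.97 at 48 h.

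By camera with all lungs, and chips averaged without further scaling, the other 16 lists were called at no time, though some were in the other fits given at single times, and single members still passed. Of 13 club cell markers, 0 were higher, 7 lower and 6 not called at 8 h (2 stable, 0 higher and 8 lower adjusted over the list alone, lowest camera adjusted p at any time 0.0975), with a median log2 change of -0.43 and with Aox3, an aldehyde oxidase, at -0.69. Of 28 cytokines and chemokines, 5 were higher, 1 lower and 22 not called at 8 h (3 stable, 7 higher and 1 lower adjusted over the list alone, lowest camera adjusted p at any time 0.216), with Ccl2, which attracts monocytes, at 1.24, and Il6, an inducer of the acute phase, at 1.18. Of 16 other antioxidant enzymes, 2 were higher, 2 lower and 12 not called at 8 h (3 stable, 2 higher and 2 lower adjusted over the list alone, lowest camera adjusted p at any time 0.0643), with Mt1 at 3.09 and Sod3, the extracellular superoxide dismutase, at -0.89, of which that of Sod3 did not pass with its next brightest probe set. Of 20 interferon-induced genes, 0 were higher, 2 lower and 18 not called at 8 h (1 stable, 0 higher and 2 lower adjusted over the list alone, lowest camera adjusted p at any time 0.321), with Gbp2 at -0.91. Of 18 genes of cholesterol and fatty acid synthesis, 4 were higher, 0 lower and 14 not called at 8 h (1 stable, 6 higher and 0 lower adjusted over the list alone, lowest camera adjusted p at any time 0.207), with Cyp51, a sterol demethylase, at 0.84, which did not pass with untreated lungs as the control. Of 17 clock genes, 3 were higher, 2 lower and 12 not called at 8 h (1 stable, 3 higher and 3 lower adjusted over the list alone, lowest camera adjusted p at any time 0.0946). Of 16 sodium and water transport genes, 2 were higher, 1 lower and 13 not called at 8 h (0 stable, 3 higher and 2 lower adjusted over the list alone, lowest camera adjusted p at any time 0.411). Among these, the water channel gene Aqp1 had a log2 change of -0.51 at 8 h, which did not pass without air replicate 3 or phosgene replicate 1 (adjusted p = 0.121 and 0.174), and Nedd4l one of 0.76, which did not pass without air replicate 2 or phosgene replicate 3 (0.0808 and 0.088) and was -0.29 with its next brightest probe set.

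Of 14 alveolar type 2 cell markers, 2 were higher, 0 lower and 12 not called at 48 h (0 stable, 4 higher and 0 lower adjusted over the list alone, lowest camera adjusted p at any time 0.261). Of 11 alveolar type 1 cell markers, 0 were higher, 2 lower and 9 not called at 8 h (1 stable, 0 higher and 3 lower adjusted over the list alone, lowest camera adjusted p at any time 0.126), with Rtkn2 at -0.79. Of 6 ciliated cell markers, 1 were higher, 2 lower and 3 not called at 8 h (1 stable, 1 higher and 3 lower adjusted over the list alone, lowest camera adjusted p at any time 0.216). Of 18 T and NK cell markers, 0 were higher, 1 lower and 17 not called at 24 h (0 stable, 0 higher and 3 lower adjusted over the list alone, lowest camera adjusted p at any time 0.0914). For 11 B cell markers, 0 were higher, 0 lower and 11 not called at 24 h (0 stable, 0 higher and 4 lower adjusted over the list alone, lowest camera adjusted p at any time 0.213). Of 6 thymocyte markers, 0 were higher, 1 lower and 5 not called at 24 h (0 stable, 0 higher and 1 lower adjusted over the list alone, lowest camera adjusted p at any time 0.246). Of 17 cardiac and skeletal muscle genes, 0 were higher, 5 lower and 12 not called at 72 h (2 stable, 0 higher and 7 lower adjusted over the list alone, lowest camera adjusted p at any time 0.139), with the atrial myosin light chain genes Myl4 and Myl7 at -0.84 and -0.91. Of 16 smooth muscle and fibroblast markers, 0 were higher, 2 lower and 14 not called at 8 h (2 stable, 0 higher and 2 lower adjusted over the list alone, lowest camera adjusted p at any time 0.053). Of 10 adipocyte markers, 1 were higher, 0 lower and 9 not called at 4 h (0 stable, 1 higher and 0 lower adjusted over the list alone, lowest camera adjusted p at any time 0.462), with the lipoprotein lipase gene Lpl at 0.99, which did not pass without air replicate 3 or phosgene replicate 1 or 2 (adjusted p = 0.0552, 0.0511 and 0.0615).

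**Figure D3:**
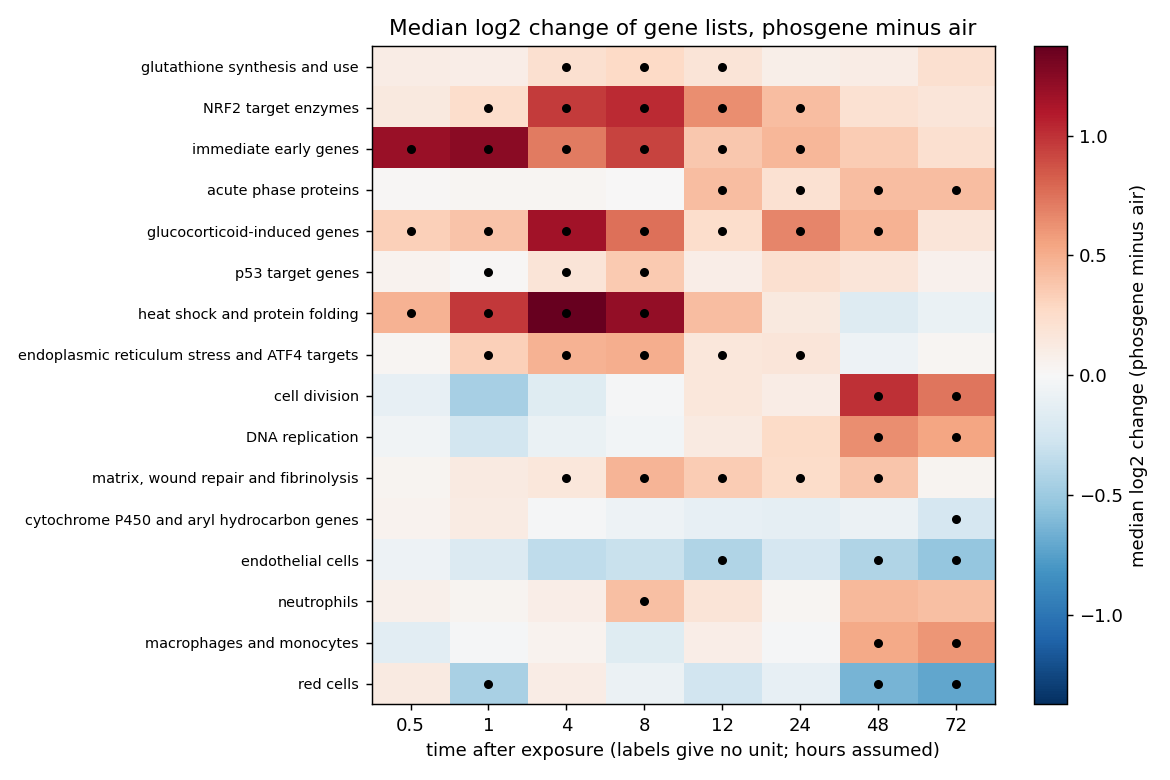
Median log2 change of the members of each of the 16 gene lists called at 1 or more times (vertical axis) at each time (horizontal axis, h), as colour, with a dot where the adjusted p was under 0.05. The immediate early list was called from 0.5 h to 24 h, and the endothelial list, lower, at 12, 48 and 72 h.

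Averaged over the 8 times, with each time weighted equally, 1191 genes were higher and 2041 lower in phosgene lungs. Hspa1a was 8.55-fold higher, Atf3 5.71-fold (log2 change 2.51 ± 0.11 SE, adjusted p = 1.88e-20), Hmox1 4.84-fold and Mt2 4.62-fold. Igfbp3 was 1.80-fold lower (log2 change -0.85 ± 0.12 SE, adjusted p = 1.13e-06) and Nrep 1.75-fold lower. The potassium channel gene Kcnk3 had a log2 change of -0.77 and Phxr4 one of -0.74, and both did not pass with untreated lungs as the control. Of the called genes 36.9% were higher, a share that was 51.9% with each chip centred on its median and 42.8% with quantile normalization. With the lung as a random block 3036 of the 3232 genes passed again in the same direction, and 2738 with hybridization day as a term. For each of the 8 hybridization days that held both phosgene and air chips, genes were chosen from the lungs with no chip on that day (2228 to 2473 genes) and read on its chips, with times mixed. Of these genes 74.9% to 90.0% kept their sign, against a mean of 49.8% to 53.1% over 99 shuffles of the exposure labels within the day, of which 0 to 7 reached the real share. Within days, the median change of the NRF2 target enzymes ran from 0.37 to 0.63, that of the heat shock list from 0.13 to 0.72 and that of the endothelial list from -0.42 to -0.19. The other 3 hybridization days held 1 chip each, and 7 chips had no scanner record and so no day.

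The test of a phosgene effect that changes with time asks which genes respond at some times more than at others, and 494 genes passed it. Arc had the largest F, 86.5, with log2 changes of 2.72 at 0.5 h, 2.57 at 1 h and -0.13 at 4 h, and the next largest were those of Hspa1b (29.4), Hmox1 (28.7) and Jun (25.5). 15 genes passed in opposite directions at different times, and all 15 also passed the test of change with time, but 0 of the 15 kept a call in each direction whichever lung was left out. Of these, Gmnn, an inhibitor of DNA replication licensing, had a log2 change of -0.60 at 8 h, lost without any 1 of 4 of the 6 lungs, and one of 0.82 at 48 h, lost without 0 of 7. Bdnf, a growth factor of neurons, had one of 0.62 at 8 h, lost without 0 of 6, and one of -0.59 at 48 h, lost without 1 of 7. With the lung as a random block 1212 genes passed, and 990 passed with hybridization day as a term. Across genes, which are not independent replicates, the log2 changes of 2 times were closest between 48 h and 72 h (Pearson r = 0.68), 4 h and 8 h (0.66), and farthest between 0.5 h and 72 h (0.04), over 28 pairs of times. Of the genes higher at 48 h, 177 were also higher at 72 h against 7.43 expected from independent draws, and 113 were lower at both against 6.21. At 4 h and 8 h, 223 genes were higher at both against 14.0 expected, and 133 lower against 15.8.

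The comparison of air lungs with untreated lungs asks which genes move with the handling, the air exposure or the time of sampling. Averaged over the 8 times, the genes of largest change included clock genes, though the 17 clock genes were not called as a list (2 higher and 5 lower, median log2 change -0.04, camera adjusted p = 0.522). The largest rise was that of Hspa1b, 2.49-fold (log2 change 1.31 ± 0.28 SE, adjusted p = 0.0282), a call lost without any 1 of untreated replicates 1, 2 and 3 (0.252, 0.143 and 0.0505) and in 4 of 16 other settings. Arntl, a core activator of the clock, was 2.17-fold higher in air lungs (log2 change 1.12 ± 0.14 SE, adjusted p = 3.65e-06), and Dbp and Nr1d1, transcription factors of its output and of its repressing loop, were lower (log2 change -1.81 ± 0.19 SE, adjusted p = 9.38e-08 for Dbp and log2 change -1.57 ± 0.26 SE, adjusted p = 0.0017 for Nr1d1). In all, 11 genes were higher and 19 lower, and these 3 are the ones among the 10 of largest change that kept their call whichever untreated lung was left out. Leaving out untreated replicate 1 gave 5 genes, with 175 genes with the lung as a random block and 171 with hybridization day as a term. Among the 8 single times, which share the 3 untreated lungs, the 17 clock genes were called lower as a list at 24, 48 and 72 h (2 higher and 5, 6 and 7 lower, camera adjusted p = 0.0332, 0.0332 and 0.0105), and no other list was called. Over the air lungs alone, 119 genes changed with time. Dbp had the largest F, 36.6, with log2 means of 6.27, 6.15, 7.92, 8.71, 7.75, 6.08, 6.05 and 6.08 from 0.5 h to 72 h and 8.68 in untreated lungs, and Arntl the next, 30.3, with 7.67, 7.59, 6.76, 6.03, 6.36, 7.72, 7.79 and 7.71 and 6.08 in untreated lungs. Per2 (25.1), Per3 (22.6) and Tef (20.1), also clock genes, and Tsc22d3 (25.7), a gene induced by glucocorticoids, followed. With the lung as a random block 529 genes changed with time in air, and 246 with hybridization day as a term.

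Single times of air against untreated gave between 0 and 188 genes. In air against untreated at 0.5 h 43 genes passed (205 with the block, 266 with the day), in air against untreated at 1 h 22 (84 and 135), and in air against untreated at 12 h 188 (583 and 112). At 4 h limma called 0 genes, with 1651 at an unadjusted p under 0.05 (26 with the block, 6 with the day). At 8 h it called 1 (37 and 10). At 24 h 20 genes passed (57 and 63), at 48 h 28 (116 and 195) and at 72 h 19 (51 with the block). Without untreated replicate 1 the counts from 0.5 h to 72 h were 14, 10, 0, 0, 26, 9, 8 and 8. Untreated replicate 2 moved the count of 1 h to 10 and that of 4 h to 1, and untreated replicate 3 moved those of 1, 8, 12 and 72 h to 7, 2, 119 and 9.

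The 2 chips of a lung correlated with a median Pearson r of 0.977 across genes (lowest 0.959), against 0.966 for chips of other lungs of the same group, and 71 of 104 chips were closest of all to the other chip of their own lung. On average over all times, signs of RNA quality did not differ detectably between phosgene and air lungs, though at 4 h the median intensity was 75.0 against 82.2 (permutation p = 0.2) and the Gapdh ratio 0.359 higher (permutation p = 0.4). The log2 ratio of 3-prime to 5-prime Gapdh signal was 0.106 higher in phosgene lungs (2-sided permutation p = 0.392), that of Actb 0.0429 higher (permutation p = 0.165), and the median intensity was 76.4 against 78.6 (permutation p = 0.0509, 0.153 after adjustment over these 3 measures). Single lungs did stand apart in this ratio: phosgene replicate 1 had the highest of its group at 0.5, 1, 4, 8, 12 and 48 h (0.75, 0.96, 0.75, 0.70, 0.37 and 0.52), and 3417 of 12393 genes moved with the ratio within groups. Leaving out that replicate gave 39, 74, 518, 493, 89 and 418 genes at these times, and whether its RNA quality is the reason was not tested. Within single times an exact 2-sided test of 3 against 3 lungs cannot go below 0.1. With the Gapdh ratio as a covariate 614 of the 683 genes of 4 h, all 1084 of 8 h, all 227 of 12 h and all 501 of 72 h passed again, and 777 genes passed at 72 h.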

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

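The splits of lungs and the shuffles of labels were fixed before the results were seen, while the tests of H2-Ea, of the clock genes and of the endothelial markers were chosen after the results they concern.

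For phosgene against air at single times, each real grouping of the lungs gave more genes than every other split, but 10 splits of 3 against 3 lungs, the real one included, are too few to rule out chance. At 0.5 h the real split gave 36 genes and the highest other 0, at 1 h 104 and 3, at 4 h 683 and 0, at 8 h 1084 and 17, at 12 h 227 and 3, at 24 h 246 and 1, and at 72 h 501 and 1, so in each case 1 of 10 splits reached the real count. At 48 h, with 3 against 4 lungs, 1 of 35 splits did (674 against a highest other of 176, the split that puts air replicate 1 with the phosgene lungs). That share lies under 0.05 for this time alone. It is the smallest that 35 splits can give and is not adjusted over the 8 times, so chance is not excluded there either.

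Over shuffled labels, 1 of 100 groupings reached the real count in each case, the real one itself. This holds for phosgene against air averaged over times (3232, highest other 114), the change of the phosgene effect with time (494, 17), the change over time in air (119, 12), air against untreated (30, 7) and the gene list shifts (56, 9).

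For air against untreated at single times, 10 splits are again too few. In 1 of 10 splits the real count was reached at 0.5 h (43, highest other 1), 1 h (22, 0), 12 h (188, 0), 24 h (20, 1) and 72 h (19, 1), in 10 of 10 at 4 h (0, highest other 2) and in 3 of 10 at 8 h (1, highest other 11). At 48 h 2 of 35 splits reached the real count of 28, with 33 for the split of air replicate 2 and the 3 untreated lungs against air replicates 1, 3 and 4, so the number of genes at that time could be a matter of chance. Of the 28, 8 are clock genes, whose mean difference was largest in the real split (1.02 log2, highest other 0.87), but that test was chosen after they were seen to differ and decides nothing. The split with 11 genes at 8 h put air replicates 1 and 2 with untreated replicate 3, and what sets those lungs apart was not tested.

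H2-Ea was 7.33-fold higher (in intensity plus 16) in phosgene lungs at 72 h. A variant of the strain or donor is a candidate explanation, because some common mouse strains do not express this gene, and it needs lungs of other groups at the same high level: 5 of the other 49 lungs lay at or above the lowest phosgene lung of 72 h (log2 8.67), 4 of them phosgene lungs of other times and 1 an air lung, while 0 of the 5 were as high in the neighbouring gene D17H6S56E-5, also higher at 72 h. The levels ran from 4.67 to 9.22, with 3 lungs between 7 and 8.5, and whether they form separate groups was not tested, while air lungs of 72 h lay between 5.83 and 6.30. A rise of the whole class II group by as much as H2-Ea (log2 2.87) is argued against by a median log2 change of 0.0599 ± 0.283 SE over the 7 others, with Cd74 at -0.03 ± 0.11 and H2-Eb1 alone over 0.5 at 1.85 ± 1.00 SE (adjusted p = 0.380), though a smaller shared rise is not excluded. Genotyping the DNA of the lungs would test the variant.

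Clock genes differed between air and untreated lungs. The mean size of the differences was 0.30 log2 at 8 h, 0.72 ± 0.20 under that at 72 h (SE over genes, not lungs). Over lungs, 0 clock genes passed at 8 h and 9 at 72 h. Dbp, Arntl, Per2, Per3 and Tef also changed with time in air. Both argue against handling and air exposure acting alike at every time, while an effect of handling that differs between times stays open. Hybridization day is also argued against as the whole cause, by the clock genes still called with the day as a term in single chips with a known day. From 0.5 h to 48 h these were 9, 9, 0, 0, 3, 6 and 11, against 9, 8, 0, 1, 6, 9 and 10 in the same chips without the term. The mean difference left at 48 h, in the direction seen without the term, was 1.06 ± 0.18 SE, again over genes (mean size 1.03 without the term). The day as a term took all genes called at 12 h from 578 to 112. The time of day of sampling could account for sizes that fall and rise again, 0.81, 0.86, 0.31, 0.30, 0.51, 0.93, 1.02 and 1.02 from 0.5 h to 72 h. Untreated lungs sampled at each clock time would test this.

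Endothelial markers were lower in phosgene lungs at 72 h, by a mean log2 of -0.52 ± 0.08 SE. A lower share of all resident lung cells might produce this, but the other resident lists stood 0.43 ± 0.07 SE above the endothelial list, with alveolar type 1 cells at -0.13, alveolar type 2 cells at 0.18, club cells at -0.13 and smooth muscle and fibroblasts at -0.25, which argues against it. The red cell and the cardiac and skeletal muscle lists lay as low (medians -0.72 and -0.55 against -0.53), so a cause shared with blood or muscle stays open. The Gapdh ratio differed by only -0.05 at 72 h, so the shift of -0.52 with it as a covariate cannot test RNA quality. How far the shift rests on the 2 of 3 air lungs numbered apart stays open. A loss of endothelial cells, or of their transcripts, after phosgene remains a hypothesis that counting such cells in sections would test.

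Of 69 values tested among the 4 air lungs of 48 h, 4 stood apart by Dixon's ratio (the gap to the nearest value over the range), and chance flags about 1 in 20 groups. They were Retnla (ratio 0.903, replicate 3 at log2 10.84 against a median of 8.68), Scube2 (0.843, replicate 1 at 8.75 against 8.10), Mad2l1 (0.945, replicate 2 at 5.56 against 5.98) and the mean of the sodium and water transport list (0.938, replicate 2 at 8.66 against 8.59).

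The phosgene effect of 494 genes changed with time, with F values of 86.5 for Arc, 29.4 for Hspa1b, 28.7 for Hmox1, 25.5 for Jun, 25.0 for Osgin1, 22.7 for Dnajb1, 21.1 for Gclc, 20.3 for Ifrd1, 19.9 for Srxn1 and 19.3 for Hsph1. Of the 494, 15 passed in opposite directions at different times, and 0 kept both calls whichever lung was left out. Of 2246 probe sets with no single gene name, 207 were called at 1 or more times.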

How the results depend on the processing

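The settings with the chip lot, the Gapdh ratio, the air lungs numbered apart and each time left out of the change with time were chosen after the data were seen, and the others before. A larger offset, or the upper 60% of genes, went with a higher correlation between times, and how far the intensity over background limits dim genes was not tested, nor was the cause of any other shift. Chips A and B are lettered by sample description, from which titles differ. Settings that keep the chips apart gave more genes in most comparisons. The fits with hybridization day or chip lot, those of lot 1 alone and those without the air lungs numbered apart compare with 1 air lung at 72 h, so their counts at 72 h, and less so over several times, rest on the spread of other groups.

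With the lung as a random block, 56 genes passed at 0.5 h, 198 at 1 h, 1102 at 4 h and 555 at 12 h. It gave 471 at 24 h, 1098 at 48 h, 904 at 72 h, 175 for air against untreated, 1212 for the effect changing with time and 529 for change in air. Hybridization day as a term gave 61 at 0.5 h, 239 at 1 h, 529 at 12 h, 546 at 24 h, 1023 at 48 h, 258 at 72 h, 171 for air against untreated, 990 for the effect changing with time and 246 in air. Chip lot as a term gave 58 at 0.5 h, 217 at 1 h, 598 at 12 h, 529 at 24 h, 1022 at 48 h, 237 at 72 h, 217 for air against untreated, 968 for the effect changing with time and 457 in air.

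Chip lot 1 alone gave 377 at 4 h, 147 at 24 h, 42 at 72 h, 17 for air against untreated, 234 for the effect changing with time, 59 in air and a mean correlation between times of 0.279. Chip A alone gave 124 at 12 h, 376 at 48 h, 268 at 72 h, 18 for air against untreated, 321 for the effect changing with time, 219 in air and a correlation of 0.297. Chip B alone gave 336 at 4 h, 580.0 at 8 h, 148 at 12 h, 117 at 24 h, 415 at 48 h, 10 for air against untreated, 280.0 for the effect changing with time, 64 in air and a correlation of 0.269. Array weights gave 1738 at 4 h, 1788 at 8 h, 525 at 24 h, 1139 at 48 h, 120.0 for air against untreated, 938 for the effect changing with time and 1200.0 in air.

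The Gapdh ratio as a covariate gave 777 at 72 h and 55 for air against untreated. Without the air lungs numbered apart, 382 genes passed at 48 h, 44 at 72 h, 57 for air against untreated, 275 for the effect changing with time and 60 in air. Only the groups compared gave 56 at 1 h, 361 at 4 h, 218 at 8 h, 44 at 12 h, 159 at 24 h, 446 at 48 h and 65 at 72 h. Requiring at least a 2-fold change left 56 at 1 h, 105 at 4 h, 158 at 8 h, 57 at 12 h, 65 at 24 h, 105 at 48 h, 71 at 72 h, 35 averaged over times and 7 for air against untreated.

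With untreated lungs as control, 181 genes passed at 0.5 h, 467 at 1 h, 413 at 12 h, 466 at 24 h and 953 averaged over times, and the log2 changes of Uts2r at 4 h (0.11) and Cxcl5 at 24 h (0.0523) turned positive without passing. With all air lungs as control, 123 passed at 0.5 h, 408 at 1 h, 2002 at 8 h, 569 at 12 h, 642 at 24 h, 1564 at 48 h and 1430.0 at 72 h, and clock genes turned, Dbp at 8 h to 0.71, which passed, and Per3 at 8 h and 12 h to 0.29 and 0.15, which did not. The next brightest probe set left 54 values of named genes the same, ended 36 calls and reversed Nedd4l at 8 h (-0.29).

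Median centring gave 161 at 24 h, and all probe sets gave 165 at 1 h and 5031 averaged over times. The change over time in air was 64 without 8 h and 63 without 12 h, and the effect changing with time 324 without 48 h. The correlation between times was 0.272 with offset 1, 0.398 with offset 64 and 0.423 for the upper 60% of genes, and the agreement of chips 0.959 with offset 1 and 0.984 with offset 64. Of the 256 list tests, camera with a preset correlation called 123 and fry 89.

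Leaving out 1 lung at a time gave 26 to 39 genes at 0.5 h, 74 to 126 at 1 h, 330.0 to 528 at 4 h, 493 to 1192 at 8 h, 89 to 273 at 12 h, 94 to 224 at 24 h, 392 to 595 at 48 h, 227 to 527 at 72 h and 5 to 45 for air against untreated, with 54 to 60 list shifts and a correlation between times of 0.327 to 0.350. Of the other values, called named genes stayed called in 5221 and lost the call in 607, and uncalled ones stayed so in 477 and passed in 53. Called lists held in 1124 and were lost in 60, and uncalled lists stayed so in 4027 and were called in 197. Genes ranked by F stayed called in all 298, and counts of air against untreated at single times moved over 1.5 times in 78 and did not in 82.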

Other observations

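In the air lungs the inducible chaperone gene Hspa1b also moved with time (F = 16.2). Its log2 mean was 8.84 at 0.5 h, 8.53 at 1 h, 6.13 at 4 h, 6.46 at 8 h, 7.55 at 12 h, 7.88 at 24 h, 8.77 at 48 h and 8.64 at 72 h, against 6.54 in untreated lungs, so its largest phosgene effect, at 4 h, stands over the lowest air level. Angptl4, an inhibitor of lipoprotein lipase, was highest in air lungs at 0.5 h (8.84) and lowest at 72 h (7.10), with F = 15.1.

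Of the markers on the endothelial list, the capillary carbonic anhydrase gene Car4 had log2 changes of -0.54 at 4 h, -0.77 at 8 h and -0.65 at 12 h (adjusted p = 0.0054, 3.49e-05 and 0.0013) and of -0.10 at 48 h (adjusted p = 0.744). The growth factor receptor gene Kdr passed at 4 h (-0.91), 8 h (-0.80), 24 h (-0.71) and 48 h (-0.52), of which the calls at 24 h and 48 h were lost without any 1 of 4 of the 6 lungs and 6 of the 7, and the difference between these genes was not tested. The epithelial keratin gene Krt8 passed at every time from 4 h on, with log2 changes of 1.00, 1.58, 1.12, 1.05, 1.19 and 0.99.

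Air replicate 1 of 1 h held far more Rag1, a recombinase gene of developing lymphocytes, than any other lung (log2 8.31 against at most 5.41 in the lungs outside that group), and more of the fat hormone gene Adipoq (9.50 against at most 8.22).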
